A study of Mus musculus with 4 samples.

How the data were processed

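Nuclear RNA was measured in 4 single-nucleus libraries of mouse thalamus, 2 from sham-operated mice and 2 from mice with mild traumatic brain injury (mTBI). Per the labels, tissue from wild-type C57BL/6 mice was dissected under a stereomicroscope from coronal slices of 300 µm and pooled, with 5 and 4 sham mice and 6 and 4 injured mice per library. The injury was a controlled cortical impact, in which a piston strikes the exposed dura, here with a tip of 3 mm at 15 degrees, a depth of 0.8 mm, a velocity of 3 m/s and a dwell of 100 ms. Sham mice had the craniotomy without the impact. The time between injury and dissection is not given in the sources used here.

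Per the labels' protocols, nuclei were purified on an iodixanol gradient, captured on a 10x Chromium instrument with the 3' v3 chemistry in 1 reaction per sample, and sequenced on an Illumina NovaSeq. Each deposited matrix holds raw UMI counts, whole numbers of distinct RNA molecules per gene and nucleus without normalization, as written by Cell Ranger 4.0.0 after its own calling of nuclei, per the file headers. The submitters' processing notes also name the genome build mm10 and Seurat 3. Whether intronic reads were counted is not given in the sources used here. A second deposited copy of each matrix held identical entries and was not used. The matrices list 32285 genes, of which 78 share a symbol with another, so genes were handled by identifier.

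The files held 11448 barcodes. Nuclei with at least 500 genes and under 1% mitochondrial UMIs were kept, which left 11308. Doublets were scored with Scrublet in scanpy 1.11.5 within each library. Its automatic thresholds called 0, 1, 5 and 393 nuclei in sham 1, sham 2, mTBI 1 and mTBI 2, so they were not used. Instead, nuclei were clustered finely (resolution 2, 35 clusters), and 10 clusters with a median doublet score above 0.08 and a median UMI count above that of all nuclei were removed as multiplets. This removed 1545 nuclei, or 13.7%, and its share per library was 23.8%, 14.3%, 19.1% and 7.18% in the same order. 9763 nuclei remained. They were normalised, 2000 variable genes were reduced to 30 principal components, and a graph of 20 neighbours was clustered with leidenalg 0.10.2 at resolution 1 (random seed 1), without batch integration, which gave 20 clusters.

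Clusters were named from 18 lists of marker genes fixed before the data were examined. A first guess came from mean CPM (UMI counts scaled to a common library total, prior 5) per nucleus, and the scores and leading genes that set the name came from summed CPM, with a minimum list score of 1. C1q chains and activation genes were kept out of the microglia markers. Names are written "X-like" because they rest on transcripts alone. 9419 nuclei had a named class. 1 cluster, whose best list (other inhibitory neurons) scored under the minimum, stayed unnamed and held 4.91% and 3.39% of the sham libraries and 2.32% and 3.20% of the mTBI libraries. The scoring rule and the multiplet rule were settled after the clusters were seen and before any test of sham against mTBI. 3 versions of each were tried. For multiplets these were Scrublet's automatic thresholds, the top-scoring share expected from loading, and the rule above. For names they were summed CPM alone with no minimum score, mean CPM per nucleus alone, and the rule above, which was written because mean CPM alone left the main reticular-like cluster unnamed. Some markers serve more than one role. Hs3st4 and Kcnip1, from the cortical and habenular lists, were among the leading genes of both reticular-like clusters, which had more markers of their own than of either list there. Ecel1 is both a reticular marker and in the axon injury list, Gpr17 is a marker of oligodendrocyte precursors and of committed precursors, Lhfpl3 is a precursor marker, Atp13a5 a mural marker and Gfap an astrocyte marker, and Atf3 is in 2 gene lists.

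UMI counts were summed per library and class, since nuclei from one pool are not replicates, and a class was tested where every library held at least 10 of its nuclei. Sham and mTBI were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood fit and test, two-sided, treatment as the only term). Adjusted p-values are Benjamini-Hochberg values over the genes tested in a class, with a threshold of 0.05. Standard errors are the size of the log2 fold change over the square root of the F statistic. CPM of single genes are scaled by TMM. The difference of the injury response between reticular-like and relay-like neurons was tested as the interaction of class and treatment in a fit with library as a term. Numbers of nuclei were tested with edgeR with total nuclei as the offset. Exact permutation tests of 2 libraries against 2 cannot go below 0.333 and tests over 4 paired libraries cannot go below 0.125.

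29 gene lists were fixed before the data were examined and 28 were tested, in classes with at least 5 measured members, with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a class. The remaining list, of sex-linked genes, served only to check the pools. All 4 pools held Y-linked transcripts and little Xist. Camera compares a list with the other genes tested in the class, so its direction is relative to them. It can differ from the signs of the members. Camera with an estimated correlation and fry were run beside the preset correlation. Of the 37 list calls, 0 held with an estimated correlation (smallest adjusted p = 0.399) and 0 with fry (smallest adjusted p = 0.414), so each list result rests on the preset correlation.

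The text names, by a rule fixed before the data were examined, the 10 largest rises and falls per reticular-like, relay-like and microglia-like class (5 in the others) among genes past the threshold with both mTBI libraries on one side of both sham libraries. Where fewer than 5 genes passed, the 5 smallest p-values are added. The rule also takes the C1q chains, the 4 smallest p-values of each passing list and of the complement, burst-firing and GABA lists, and the 5 smallest p-values of the interaction. Genes named outside it are said to be so, and some that it takes are not reported here. Predicted genes were passed over. Positions come from GENCODE M21 on GRCm38, the mouse build also called mm10. 20 of 32 genes looked up overlap another gene. Whether counting used strand is not given in the sources used here, so genes that overlap another are uncertain.

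Labels state that replicates 1 and 2 were run on different Chromium runs, so replicate numbers pair the samples by run. Deviations of same-numbered libraries from their group means correlated between -0.0234 and 0.132 across classes. The replicate block was run as an alternative. Other alternatives set before the data were examined were RLE size factors, DESeq2 1.42.0, no low-count filter, counts thinned to the shallowest library, doublets kept, a lower clustering resolution of 0.4, a minimum of 1000 UMIs and leaving out each library. With doublets kept, clusters with markers of more than 1 family of cell types were named too, where the main rule left such clusters unnamed. Microglia-like nuclei then took in clusters of 104 and 85 nuclei beside 421. Their median doublet scores were 0.133 and 0.0979, against 0.0061, so the class was another population there. Added after seeing the data were the other naming versions, leaving out clusters with over 80% of nuclei from 1 library, and the list tests without each library, with doublets kept and under the naming from summed CPM alone. No pair of libraries agreed within sampling noise, with chi-square over degrees of freedom of 3.50 to 13.7 across pairs.

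The edgeR step was tested on simulated counts with 200 changed genes, drawn from those past the low-count filter. All genes of a class were given the same dispersion, the spread between libraries beyond counting error, and no run effect was simulated. The rates below hold for that setting and do not give the recovery or the false calls of the real comparison. In relay-like neurons it recovered 67.4% of genes changed by 1 on the log2 scale and 91.6% of those changed by 2, and in microglia-like nuclei 26.2% and 85.2%. In reticular-like neurons it recovered 55.2% and 93.9%, in astrocyte-like nuclei 23.4% and 90.1%, in oligodendrocyte-like nuclei 54.1% and 91.5%, and in precursor-like nuclei 33.3% and 85.2%. False calls were between 2.75% and 6.45% of calls in these classes and 7.78% in all nuclei summed. Shares of nuclei carry 95% Clopper-Pearson intervals, which cover counting error only.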

Results

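Nuclear transcriptomes were measured in the nucleus reticularis of the mouse thalamus (nRT), a shell of GABAergic neurons that inhibits the relay nuclei, together with the adjoining relay thalamus. There were 2 groups of 2 libraries, sham and mild traumatic brain injury (mTBI), each library a pool of 4 to 6 mice. The series title concerns complement factor C1q, lost sleep spindles and epileptic spikes after mild injury. Sham 1 and sham 2 held 24940826 and 28108937 UMIs in 2337 and 3891 barcodes. mTBI 1 held 8098708 UMIs in only 645 barcodes and mTBI 2 held 29780811 in 4575, so values of mTBI 1 rest on the fewest nuclei. Median UMIs per barcode were 4184, 3207, 4844 and 3713, in the order sham 1, sham 2, mTBI 1 and mTBI 2, which is kept below. After filters, 1753, 3301, 518 and 4191 nuclei were used. The 2 pools of a group were on different Chromium runs and differed in yield. The spread behind the p-values of the main fit therefore mixes pools of mice, runs and numbers of nuclei.

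The dissections were made up mainly of oligodendrocyte-like nuclei, at 49.0% ± 4.06 of nuclei in sham and 47.4% ± 10.0 in mTBI (mean ± SD, n = 2 libraries each), and of relay-like glutamatergic neurons, at 21.9% ± 1.06 and 23.7% ± 7.28. Reticular-like GABAergic neurons made up 7.14% ± 3.96 and 8.79% ± 3.97, astrocyte-like nuclei 5.75% ± 2.41 and 4.27% ± 0.577, and microglia-like nuclei 3.69% ± 0.614 and 4.85% ± 0.242. Oligodendrocyte precursor-like nuclei (3.26% ± 0.547 and 2.69% ± 0.293), committed precursor-like nuclei (2.44% ± 0.498 and 3.06% ± 1.40) and endothelial-like nuclei (1.53% ± 0.0651 and 1.09% ± 0.365) were rarer. No class passed a test of its share between groups, with a smallest adjusted p of 0.738 by edgeR over the class counts, and the exact permutation test of 2 libraries against 2 cannot go below 0.333.

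**Figure D1:**
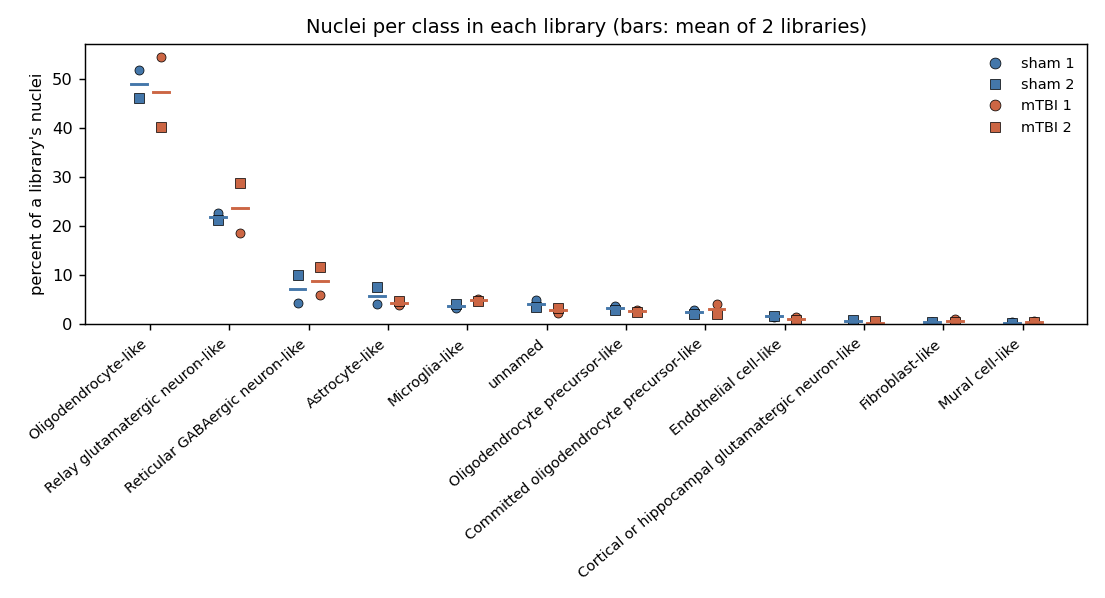
Percent of each library's nuclei in each class, with bars for the mean of 2 libraries and a point for each library, sham and mTBI side by side. Oligodendrocyte-like nuclei were the most frequent in both groups and the points of the groups lie close together or overlap in most classes.

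In reticular-like neurons, 5 genes passed between mTBI and sham. Gria1, which encodes the GluA1 subunit of AMPA glutamate receptors, fell by 1.41 ± 0.18 on the log2 scale (SE, n = 2 libraries per group, adjusted p = 0.0172), from 130 and 114 CPM in sham to 48.7 and 44.5 in mTBI. Myocd, a transcriptional coactivator of smooth muscle genes, rose 3.07-fold (log2 1.62 ± 0.23, adjusted p = 0.0269), from 29.5 and 22.6 CPM to 85.8 and 72.0. Expression of mt-Co3 of the mitochondrial genome fell by 1.10 ± 0.18 (adjusted p = 0.0447). Bcas1os2, an antisense RNA of the oligodendrocyte gene Bcas1, fell by 4.24 ± 0.65 (adjusted p = 0.0377), with 16 and 41 UMIs in sham and 0 and 4 in mTBI. It is uncertain because the counts of both genes may share reads. Bcas1os2 was also among the leading genes of the committed precursor-like cluster. Oligodendrocyte markers were lower in reticular-like neurons in mTBI too, as given below.

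Gria1 (ENSMUSG00000020524) lies on the plus strand of chromosome 11 from 57011387 to 57330244 in GRCm38 and Myocd (ENSMUSG00000020542) on the minus strand of chromosome 11 from 65176561 to 65269989. No other annotated gene overlaps either. mt-Co3 overlaps mt-Atp6 and is uncertain for that reason. Nuclear counts summed over whole genes do not tell exons from introns.

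These calls were made among 12334 genes, of which 505 had an unadjusted p under 0.05. With the replicate block 22 genes passed, of which 21 fell. RLE size factors and a minimum of 1000 UMIs gave 3 genes each, DESeq2 1, and UMIs thinned to the shallowest library or doublets kept 0 by edgeR (317 and 414 at an unadjusted p under 0.05). Under the other settings Gria1 passed in 10 of 12 (adjusted p from 1.29e-10 to 0.444), Myocd in 8 of 12 (3.12e-08 to 0.603), Bcas1os2 in 7 of 11 (3.61e-07 to 1.00) and mt-Co3 in 4 of 12 (1.04e-07 to 0.992). Gria1 did not pass with UMIs thinned (adjusted p = 0.366, at -1.46) or with doublets kept (0.444, at -1.21), where Bcas1os2 was at -1.55. By library, calls ended for Myocd without sham 2 (adjusted p = 0.0873), for Bcas1os2 without sham 2 (1.00) or mTBI 2 (0.0926), and for mt-Co3 without sham 1 (0.115), sham 2 (0.148) or mTBI 2 (0.106), while 26 genes passed without sham 2, 196 without mTBI 1 and 45 without mTBI 2.

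Of 23 measured glutamate receptor genes in reticular-like neurons, Gria1 alone fell, over all genes and adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.646, median log2 0.02, mean -0.11, test downward). Burst-firing channels, the T-type calcium, HCN and SK channels and partners that shape rhythmic bursting, did not pass either (24 measured, 8 higher and 16 lower, median -0.08, adjusted p = 0.316), with 0 genes adjusted over the list alone by edgeR. Among them the values were -1.23 ± 0.45 for the SK channel Kcnn3, 0.20 ± 0.09 for Kcnma1 and -0.53 ± 0.26 for Pex5l. The GABA list did not pass (21 measured, adjusted p = 0.851, median 0.03, mean -0.02, test upward), with 0 genes adjusted over the list alone. Its smallest p-values were those of Gad1 (0.50 ± 0.17), Gabrb2 (-0.49 ± 0.19) and Slc32a1 (0.61 ± 0.25). Of 11 complement genes 0 passed and 5 were higher (list adjusted p = 0.823), with Csmd3 at -0.27 ± 0.16, Cfp at -0.42 ± 0.37, Csmd2 at 0.14 ± 0.14 and Csmd1 at -0.09 ± 0.10.

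The myelin list fell in reticular-like neurons (12 of 15 measured members lower, median log2 -0.49, adjusted p = 2.79e-07, and adjusted p = 0.908 with an estimated correlation). Mbp (-1.67 ± 0.41) and Gjc3 (-1.94 ± 0.57) passed adjusted over the list alone, Aspa was at -1.35 ± 0.48 and Mobp at -1.23 ± 0.49, and 0 members passed over all genes. Mbp passed over all genes with the replicate block (adjusted p = 0.0354). Oligodendrocyte markers summed to 1109 and 517 unscaled CPM in sham and 398 and 458 in mTBI in these neurons, a ratio of 0.527. Without sham 1 the list's adjusted p was 0.410.

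In relay-like neurons, which send thalamic output to cortex, 1 gene passed. Creb5, a transcription factor of the CREB and ATF family, rose 3.69-fold (log2 1.88 ± 0.16, n = 2 libraries per group, adjusted p = 0.00778), from 19.9 and 19.6 CPM in sham to 83.3 and 65.8 in mTBI. The gene (ENSMUSG00000053007) lies on the plus strand of chromosome 6 from 53287270 to 53700376, where 2 predicted genes overlap it. The next smallest p-values did not pass. They were those of Kcnj3, a subunit of G-protein-gated potassium channels (-0.89 ± 0.11, adjusted p = 0.0637, from 624 and 642 CPM to 365 and 319), the endopeptidase-like gene Ecel1 (4.44 ± 0.54, adjusted p = 0.0637, from 1 and 3 UMIs to 10 and 103), Cntnap5b (-1.15 ± 0.16, adjusted p = 0.108) and mt-Co2 (-1.02 ± 0.14, adjusted p = 0.108). Reticular markers summed to 298 and 303 unscaled CPM in sham and 276 and 398 in mTBI in this class, and Ecel1 is among those markers. Cluster 4 held more relay-like nuclei than any other cluster in each library.

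Of 15712 genes tested in relay-like neurons, 1151 had an unadjusted p under 0.05. With the replicate block 290 genes passed, of which 119 rose and 171 fell, and DESeq2 called 25. Among those of the block were Kcnj3 (adjusted p = 1.11e-11), Ecel1 (2.41e-09) and Cntnap5b (2.36e-19). Creb5 passed in 11 of 13 other settings (adjusted p from 8.77e-27 to 0.895), and its call ended with doublets kept (log2 0.42, adjusted p = 0.895) and with thinned UMIs (0.193). The count was 17 without sham 1, 2 without sham 2, 837 without mTBI 1 and 155 without mTBI 2.

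The axon injury list rose in relay-like neurons, with 13 of 13 measured members higher (median log2 0.22, adjusted p = 8.46e-05, and adjusted p = 0.934 with an estimated correlation). Adjusted over the list alone, Jun (1.2 ± 0.25), Ecel1 and Atf3, a stress-induced transcription factor with 1 and 1 UMIs in sham and 5 and 40 in mTBI, passed, and over all genes 0 did. Stmn4 was at 0.56 ± 0.20. Without mTBI 2 the list's direction against the other genes turned downward, so the rise of the list depended on mTBI 2. The named members did not turn without any library, with lowest log2 values of 4.10 for Ecel1, 3.79 for Atf3, 0.62 for Jun and 0.06 for Stmn4. Cluster 14 held 174 nuclei with a median of 2082.5 UMIs, 20 and 34 of them in sham and 6 and 114 in mTBI. In mTBI 1 and mTBI 2 it held 9 of 10 and 86 of 103 Ecel1 UMIs, 2 of 5 and 32 of 40 of Atf3 and 3 of 42 and 81 of 508 of Jun. Its values in mTBI 1 thus rest on 6 nuclei. Under the naming from summed CPM alone, added after the data were seen, which leaves this cluster out, Ecel1 and Atf3 had too few UMIs to be tested, Jun was at 1.03 and the list did not pass (11 measured, adjusted p = 0.338). The p53 and apoptosis list also rose (10 of 14 higher, median 0.14, adjusted p = 0.0266, and adjusted p = 0.934 with an estimated correlation), with 3 members passing adjusted over the list alone, among them Bbc3 (2.54 ± 0.54) and Bcl2l11 (1.2 ± 0.23), 0 over all genes and Phlda3 at 0.83 ± 0.47. Bbc3 and Bcl2l11 encode pro-apoptotic BH3-only proteins. With the replicate block Jun (adjusted p = 9.71e-05), Atf3 (0.000108), Stmn4 (0.012), Bbc3 (0.00142) and Bcl2l11 (0.00157) passed over all genes, while the p53 and apoptosis list did not pass (0.119), nor did it without cluster 14 (0.296, with Bcl2l11 at 0.78 and Bbc3 at 2.25), with doublets kept (0.366), without sham 1 (0.161) and without mTBI 2 (0.183). Cluster 14 held 7 of 33 and 60 of 212 Bcl2l11 UMIs of the mTBI libraries. It also held 23 of 172 and 193 of 930 Creb5 UMIs of these libraries, against 2 of 111 and 4 of 164 in sham. Creb5 still passed by edgeR without this cluster (log2 1.65, adjusted p = 0.0336).

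Among 25 burst-firing channel genes in relay-like neurons, Kcnj3 and Kcnt2 (0.88 ± 0.18) passed adjusted over the list alone and 0 over all genes, with Kcnn2 at -0.43 ± 0.12 and Kcnk2 at 0.86 ± 0.32. The list did not pass (adjusted p = 0.618, median 0.05, mean 0.04, test downward). The GABA list did not pass (22 measured, adjusted p = 0.883, median 0.09, mean 0.02, test downward), with 0 genes adjusted over the list alone and values of -0.40 ± 0.10 for Gabra4, 0.38 ± 0.17 for Gabra2, 0.53 ± 0.24 for Gabra3 and -0.21 ± 0.11 for Gabrb2. Kcnt2 (adjusted p = 3.60e-07), Kcnn2 (0.0138) and Gabra4 (0.0284) passed over all genes with the replicate block. Of 16 complement genes 11 were higher and 0 passed (list adjusted p = 0.279). They included Csmd2 (0.46 ± 0.18), Susd4 (0.34 ± 0.14), C1qa (0.94 ± 0.61, 4 to 26 UMIs per library) and Cd59a (0.49 ± 0.40).

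The injury response differed between reticular-like and relay-like neurons for 16 genes by a test of the difference itself. Creb5 stood at 0.07 in reticular-like and 1.88 in relay-like neurons on the log2 scale, a difference of -1.76 ± 0.19 (adjusted p = 0.000157, n = 4 libraries with both classes). Gria1 stood at -1.41 and 0.22 (difference -1.69 ± 0.18, adjusted p = 0.000157), the ubiquitin ligase-like gene Pdzrn4 at -0.56 and 0.91 (-1.51 ± 0.20, adjusted p = 0.00329), Ecel1 at 0.05 and 4.44 (-4.41 ± 0.65, adjusted p = 0.0065) and Luzp2 at -0.81 and 0.35 (-1.21 ± 0.18, adjusted p = 0.0065). Outside the naming rule, chosen after their values were seen, Kcnj3 differed by 0.85 and Cntnap5b by 1.04. 0 of the 5 passed without mTBI 2 (adjusted p of 0.0755, 0.350, 0.780, 0.780 and 0.791 for Creb5, Gria1, Pdzrn4, Ecel1 and Luzp2), where 0 genes passed in all, against 36 without sham 1, 71 without sham 2 and 69 without mTBI 1. With doublets kept 0 genes passed, and the differences were -0.44 for Creb5, -1.35 for Gria1, -0.36 for Pdzrn4, -0.88 for Ecel1 and -0.59 for Luzp2. Naming from summed CPM alone, which leaves cluster 14 out of the relay-like class and was added after the data were seen, cut the difference of Ecel1 to -1.89 and ended its call (adjusted p = 0.851, from 4.49e-10 to 1.00 over its alternatives). Cntnap5b did not pass there either (1.02, adjusted p = 0.0619).

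In microglia-like nuclei, 11 genes passed, of which 10 rose. Apoe, the lipid carrier induced in disease-associated microglia, rose 3.41-fold (log2 1.77 ± 0.28, n = 2 libraries per group, adjusted p = 0.0143), from 1040 and 513 CPM in sham to 1891 and 3014 in mTBI. The unconventional myosin Myo1e rose 3.94-fold (1.98 ± 0.34, adjusted p = 0.0264), the actin nucleator Fmn1 3.25-fold (1.70 ± 0.30, adjusted p = 0.0321) and the adhesion molecule Cadm1 2.07-fold (1.05 ± 0.19, adjusted p = 0.0387, from 657 and 660 CPM to 1446 and 1314). Nhs, a regulator of actin remodelling, fell by 1.83 ± 0.28 (adjusted p = 0.0143), from 454 and 466 CPM to 111 and 135. Rai14 (3.19 ± 0.63, from 2 and 2 UMIs to 8 and 45) and Anapc15 (1.34 ± 0.26) each had an adjusted p of 0.0396, and Anapc15 is uncertain because Folr1 and Tomt overlap it on the other strand.

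A further 4 of the genes that rose in microglia-like nuclei were abundant in sham astrocyte-like nuclei, at 3737 to 7812 CPM. They were Npas3 (3.61 ± 0.71, from 4 and 3 UMIs to 44 and 48, adjusted p = 0.0396), Ntm (3.04 ± 0.58, from 1 and 7 to 27 and 48, adjusted p = 0.0396), Wdr17 (from 0 and 3 UMIs to 41 and 39, adjusted p = 0.0396) and Trpm3 (from 0 and 2 UMIs to 47 and 32, adjusted p = 0.0418). Apoe (a mean of 1715 against 617 unscaled CPM) and Myo1e (122 against 70.4) too stood higher in sham astrocyte-like than in sham microglia-like nuclei, and Fmn1 stood higher in sham reticular-like neurons (280 against 115). Astrocyte markers summed to 648 and 688 unscaled CPM in sham and 1800 and 988 in mTBI in microglia-like nuclei, a ratio of 2.08. Precursor markers went from 191 and 107 to 570 and 417, a ratio of 3.32, and mural markers from 191 and 344 to 12.7 and 104, a ratio of 0.217.

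Apoe (ENSMUSG00000002985) lies on the minus strand of chromosome 7 from 19696109 to 19699188, Nhs (ENSMUSG00000059493) on the minus strand of chromosome X from 161833296 to 162159730, and Cadm1 (ENSMUSG00000032076) on the plus strand of chromosome 9 from 47530173 to 47857637. Nhs, Cadm1, Fmn1, Rai14, Npas3, Ntm, Wdr17 and Trpm3 overlap predicted or noncoding genes. In microglia-like nuclei 4023 genes were tested and 308 had an unadjusted p under 0.05. The replicate block called 60 genes, of which 39 rose. With UMIs thinned to the shallowest library 0 genes passed by edgeR, with Apoe, Myo1e, Cadm1 and Nhs at an adjusted p of 0.194 each. 0 of the 11 passed under DESeq2, where 74 genes had an unadjusted p under 0.05, with doublets kept (370), with a minimum of 1000 UMIs (290) or without mTBI 1 (357, each adjusted p = 0.739). Over their other settings the highest adjusted p of these genes lay between 0.793 for Anapc15 and 0.999. With doublets kept the log2 values were 0.09 for Trpm3, 0.37 for Wdr17, 0.12 for Npas3, -0.10 for Ntm, 0.78 for Fmn1, -0.73 for Nhs, 1.46 for Myo1e, 2.06 for Rai14, 0.95 for Cadm1, 1.99 for Apoe and 1.74 for Anapc15. Fmn1 did not pass without mTBI 2 (adjusted p = 0.237), nor Anapc15 (0.0875) and Rai14 (0.483) without sham 2. In all, 36 genes passed without sham 1, 18 without sham 2 and 65 without mTBI 2.

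The disease-associated microglia list rose in microglia-like nuclei (11 of 13 measured members higher, median log2 1.28, adjusted p = 2.65e-11, and adjusted p = 0.503 with an estimated correlation). Of its members 9 passed adjusted over the list alone, and 1, Apoe, over all genes. Among the 9 were the growth factor Igf1 (2.93 ± 0.68), the tetraspanin Cd9 (1.34 ± 0.31) and the chemokine Ccl4, with 0 UMIs in both sham libraries and 6 and 26 in mTBI, and these 3 passed over all genes with the replicate block (adjusted p = 0.00825, 0.000495 and 0.000265). Homeostatic microglia genes fell as a list (11 of 12 lower, median -0.34, adjusted p = 0.000400, and adjusted p = 0.503 with an estimated correlation), with 0 members passing adjusted over the list alone. Gpr34 was at -0.71 ± 0.22, Selplg at -0.61 ± 0.22, Sall1 at -0.74 ± 0.28 and Slc2a5 at -1.03 ± 0.49. The disease-associated list rose beside the astrocyte and precursor markers given above. Its adjusted p was 0.101 without mTBI 2 and 1.71e-24 with doublets kept, where the homeostatic list did not pass (0.751).

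Synaptic adhesion genes rose as a list in microglia-like nuclei (10 of 10 higher, median 1.10, adjusted p = 1.25e-06, and adjusted p = 0.399 with an estimated correlation). Of its members 3 passed adjusted over the list alone, including Nlgn1 (3.29 ± 0.80) and Lrrc4c (1.58 ± 0.52), over all genes 0 did, and Cadm2 was at 1.13 ± 0.48. With doublets kept the list turned (31 measured, adjusted p = 0.000635), with Nlgn1 at -0.17, Lrrc4c at -0.16, Cadm2 at -0.30 and Gabrb1 at -0.59. That setting added clusters of 104 and 85 nuclei with higher doublet scores to the class. Nlgn1 (adjusted p = 0.000539), Lrrc4c (0.0389) and the GABA receptor gene Gabrb1 (0.0154) passed over all genes with the replicate block. The listed genes encode adhesion proteins of synapses, and the list rose beside the astrocyte and precursor markers given above. Sodium and potassium channels did not pass there (6 measured, adjusted p = 0.134), but passed with the replicate block (adjusted p = 0.0446), and passed downward with doublets kept (0.0127). The GABA and burst-firing lists had too few measured members for a test, with Gabrb1 at 2.17 ± 0.65, Gabbr1 at 0.23 ± 0.49, Gphn at 0.10 ± 0.31, Slc12a2 at 0.10 ± 0.38, Pex5l at -1.40 ± 0.48, Atp2a2 at 0.31 ± 0.30 and Kcnma1 at 0.09 ± 0.23.

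The C1q chains, which form the recognition molecule of the classical complement pathway, passed no test between mTBI and sham in microglia-like nuclei. C1qa stood at 358 and 348 CPM in sham and 191 and 708 in mTBI (log2 0.61 ± 0.35, adjusted p = 0.728 over all genes and 0.340 adjusted over the list alone). C1qb stood at 215 and 212 against 175 and 325 (0.39 ± 0.31, adjusted p = 0.854 and 0.456), and C1qc at 155 and 136 against 63.6 and 263 (0.50 ± 0.43, adjusted p = 0.891 and 0.456). The mTBI libraries lay on either side of sham for each chain, and without mTBI 2 the values were -0.91, -0.32 and -1.19. In mTBI 1 the chains rest on 12, 11 and 4 UMIs of C1qa, C1qb and C1qc in 26 nuclei. In mTBI 2 there were 194, 89 and 72 UMIs in 196 nuclei, so the low side is that of a sparse library. The genes lie side by side on the minus strand of chromosome 4, C1qb from 136880129 to 136886187, C1qc from 136889804 to 136893065 and C1qa from 136895917 to 136898803. In all nuclei summed C1qa was at 0.50 ± 0.31, C1qb at 0.73 ± 0.30 and C1qc at 0.77 ± 0.36, each with an adjusted p of 1.00. Of 7 measured complement genes in microglia-like nuclei, Csmd3 passed adjusted over the list alone (-0.78 ± 0.16, adjusted p = 0.057 over all genes and 0.0064 with the replicate block), and the list did not pass (adjusted p = 0.616, median 0.29, mean 0.14, test downward), but passed upward with doublets kept (18 measured, 0.0415).

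C1q transcripts came mainly from microglia-like nuclei, which held 48.8%, 65.6%, 56.3% and 69.7% of all C1q UMIs of the 4 libraries, or 60.1% ± 9.40 (SD, n = 4). The level in this class was 582, 549, 342 and 1050 CPM and exceeded that of each class with nuclei in every library in 4 of 4 libraries (exact permutation p = 0.125, the smallest that 4 pairs allow), and that of cortical or hippocampal glutamatergic-like neurons, absent from mTBI 1, in the other 3. Oligodendrocyte-like nuclei held 15.2%, 8.89%, 22.9% and 13.2% of C1q UMIs and endothelial-like nuclei 16.8%, 12.8%, 2.08% and 0.393%. A C1q UMI was found in 59.6% of microglia-like nuclei of sham 1 (95% Clopper-Pearson interval 45.8% to 72.4%), 55.9% of sham 2 (47.1% to 64.4%), 65.4% of mTBI 1 (44.3% to 82.8%) and 69.4% of mTBI 2 (62.4% to 75.8%). With each nucleus thinned to 1000 UMIs, which left out 3, 11, 0 and 13 nuclei, the shares were 48.1%, 48.0%, 38.5% and 56.3%. In oligodendrocyte-like nuclei, which should lack C1q, the shares were 1.98%, 1.05%, 3.55% and 3.85%, and 0.480%, 0.405%, 0.355% and 1.95% after thinning, which left out 75, 39, 0 and 46 nuclei. Median depths were 1665, 1447.5, 2448.5 and 1645 UMIs in microglia-like and 2231, 1908, 3218 and 1988 in oligodendrocyte-like nuclei.

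**Figure D2:**
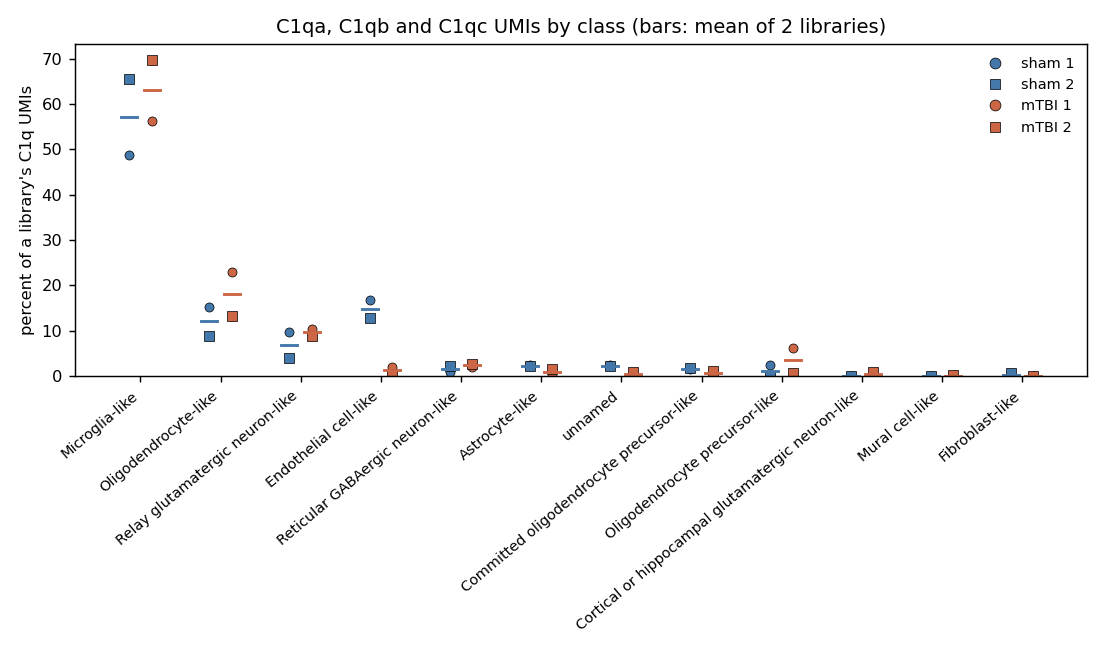
Percent of each library's C1qa, C1qb and C1qc UMIs found in each class, with bars for the mean of 2 libraries and a point for each library of sham and mTBI. Microglia-like nuclei held the largest share in each library, from 48.8% to 69.7%.

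In astrocyte-like nuclei, 10 genes passed, and in 6 of them both mTBI libraries lay on one side of both sham libraries. The orphan receptor gene Gpr37l1 rose 2.13-fold (log2 1.09 ± 0.24, n = 2 libraries per group, adjusted p = 0.031), from 227 and 221 CPM in sham to 338 and 545 in mTBI, and Fmn1 rose by 3.25 ± 0.60 (adjusted p = 0.00284, from 2 and 4 UMIs to 5 and 45). Lhfpl3, a precursor marker, rose from 1 and 2 UMIs to 8 and 35 (adjusted p = 0.00186), and the mural marker Atp13a5 rose 2.97-fold (1.57 ± 0.35, adjusted p = 0.042). The mitochondrial genes mt-Co1 and mt-Co3 fell by 1.80 ± 0.28 (adjusted p = 0.000236) and 1.26 ± 0.29 (adjusted p = 0.0428). Mural markers summed to 204 and 154 unscaled CPM in sham and 322 and 314 in mTBI in these nuclei, while precursor markers had a ratio of 1.02. The other 4, chosen after their values were seen, were Nrg3 (2.10 ± 0.41), Snhg11 (1.48), Unc5c (1.53) and the astrocyte filament gene Gfap (1.23 ± 0.28, 174 and 108 CPM in sham against 142 and 378 in mTBI), whose groups overlapped. mTBI 1 held 20 astrocyte-like nuclei.

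Of 7139 genes tested in astrocyte-like nuclei 305 had an unadjusted p under 0.05, and 0 genes passed under DESeq2 (33) or with doublets kept (285, with Fmn1 at 1.18 and mt-Co1 at -1.25). Across 10 or 11 other settings each, mt-Co1 passed in 8 (adjusted p from 5.50e-12 to 1.00), Fmn1 in 7, Lhfpl3 in 6, and Gpr37l1, Atp13a5 and mt-Co3 in 5. Without sham 1 calls ended for Gpr37l1 (adjusted p = 0.749), Atp13a5 (0.10) and mt-Co3 (0.999), without sham 2 for Gpr37l1, Atp13a5, Lhfpl3 and Fmn1 (0.998 each), and without mTBI 2 for Gpr37l1 (0.654), Atp13a5 (0.0811), mt-Co1 (0.269) and mt-Co3 (0.404). With the replicate block 6 genes passed, and Gpr37l1 (adjusted p = 0.0723) and mt-Co3 (0.181) did not. Without sham 1, sham 2 or mTBI 2 there were 5, 3 and 3 genes, and 68 without mTBI 1.

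Interferon response genes rose as a list in astrocyte-like nuclei (4 of 5 measured members higher, median log2 0.95, adjusted p = 0.000135, and adjusted p = 0.693 with an estimated correlation). The antiviral gene Oasl2, with 1 and 1 UMIs in sham and 10 and 16 in mTBI, and Stat2 (1.45 ± 0.50) passed adjusted over the list alone and 0 over all genes, with Ddx58 at 0.95 ± 0.53 and Eif2ak2 at 0.74 ± 0.53. Oasl2 passed over all genes with the replicate block (adjusted p = 0.00589). The disease-associated oligodendrocyte list (4 of 5 higher, median 1.09, adjusted p = 0.00273, and adjusted p = 0.693 with an estimated correlation) had 0 members adjusted over the list alone, with C4b at 1.09 ± 0.47, B2m at 2.27 ± 0.87, H2-K1 at 1.16 ± 0.65 and Cd63 at 0.64 ± 0.30. The disease-associated microglia list (9 of 10 higher, median 0.63, adjusted p = 0.00771, and adjusted p = 0.825 with an estimated correlation) had Apoe alone adjusted over the list alone (0.67 ± 0.21) and Ctsl at 0.73 ± 0.37. It did not pass without sham 2 (adjusted p = 0.339) and turned without mTBI 2 (0.0779), where Apoe was at -0.06 and Ctsl at -0.10, and Eif2ak2 was at -0.04 without sham 2.

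Synaptic adhesion genes in astrocyte-like nuclei (16 of 23 higher, median 0.21, adjusted p = 0.00278, and adjusted p = 0.693 with an estimated correlation) had 0 members adjusted over the list alone, with Cntnap2 at 1.09 ± 0.38, Ntng1 at 1.11 ± 0.39, Tenm4 at 0.81 ± 0.41 and Nlgn2 at 1.30 ± 0.67, and the list did not pass without sham 2 (adjusted p = 0.0863) or mTBI 2 (0.0588), where Cntnap2 turned to -2.36 and Ntng1 to -0.63. Of 9 complement genes Clu, which encodes a complement-binding chaperone, passed adjusted over the list alone (0.75 ± 0.24), and the list did not pass (adjusted p = 0.289), with Susd4 at -1.38 ± 0.68 and Csmd1 at 0.47 ± 0.32. Without mTBI 2 Clu turned to -0.18 and Csmd1 to -1.43. The GABA list (14 measured, adjusted p = 0.711) had 0 members adjusted over the list alone, with the GABA transporter Slc6a11 at 0.35 ± 0.19, Gabrb2 at 0.66 ± 0.47 and Gphn at -0.27 ± 0.20. The burst-firing list did not pass either (9 measured, adjusted p = 0.794), with Kcnk1 at 1.17 ± 0.48, Kcnj3 at -0.94 ± 0.43, Pex5l at 0.99 ± 0.49 (-0.49 with doublets kept) and Atp2a2 at 0.28 ± 0.22.

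In oligodendrocyte-like nuclei, C4b rose and Sgk1 fell. C4b, the mouse complement component 4 that C1s cleaves downstream of C1q, rose 18.3-fold (log2 4.19 ± 0.41, n = 2 libraries per group, adjusted p = 0.0213), from 3.20 and 3.29 CPM in sham to 37.2 and 76.1 in mTBI, or from 7 and 10 UMIs to 36 and 282. Sgk1, a kinase gene induced by glucocorticoids, fell by 1.86 ± 0.21 (adjusted p = 0.0378), from 103 and 117 CPM to 22.8 and 34.0. C4b (ENSMUSG00000073418) lies on the minus strand of chromosome 17 from 34728380 to 34743882 and Sgk1 (ENSMUSG00000019970) on the plus strand of chromosome 10 from 21882184 to 21999903. C4b has a near-identical copy, C4a, with 0, 2, 0 and 1 UMIs in these nuclei, so the assignment of reads between the copies is uncertain. The next smallest p-values did not pass. They were those of Alpk1 (3.41 ± 0.52, adjusted p = 0.225, from 3 and 3 UMIs to 14 and 44), Kcnab1 (0.90 ± 0.15, adjusted p = 0.35) and Zbtb16 (-1.47 ± 0.27, adjusted p = 0.639).

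C4b passed in 12 of 12 other settings, with an adjusted p of at most 0.0366. Sgk1 passed in 10 of 12 and not with RLE size factors (adjusted p = 0.0501) or without the cluster that comes mostly from mTBI 2 (0.0528). Of 12255 genes 467 had an unadjusted p under 0.05, DESeq2 called 5, and 16, 8, 448 and 378 passed without sham 1, sham 2, mTBI 1 and mTBI 2. Cluster 1 held the most oligodendrocyte-like nuclei in sham 1, sham 2 and mTBI 1 and cluster 0 in mTBI 2, and 87.3% of cluster 7 came from mTBI 2.

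The disease-associated oligodendrocyte list rose in oligodendrocyte-like nuclei (7 of 7 measured members higher, median log2 0.68, adjusted p = 1.09e-14, and adjusted p = 0.646 with an estimated correlation). Adjusted over the list alone C4b, the alarmin Il33 (0.49 ± 0.17), the MHC class I gene H2-K1 (1.21 ± 0.46) and Cd63 (1.13 ± 0.26) passed, and C4b alone over all genes. The complement list rose (12 of 14 higher, median 0.20, adjusted p = 9.75e-05, and adjusted p = 0.646 with an estimated correlation), with C4b alone passing, both over all genes and adjusted over the list alone. Cd46 was at 0.45 ± 0.19, Susd4 at 0.65 ± 0.34 and C1qa at 0.85 ± 0.49, and without mTBI 2 the list's adjusted p was 0.0638. The disease-associated microglia list rose (12 of 12 higher, median 0.48, adjusted p = 4.50e-05, and adjusted p = 0.646 with an estimated correlation), with Apoe (0.87 ± 0.21), Ctsd (0.93 ± 0.30) and Cd63 passing adjusted over the list alone, 0 over all genes and Cd9 at 0.49 ± 0.20. It turned without mTBI 2 (adjusted p = 0.85).

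The glucocorticoid response list fell in oligodendrocyte-like nuclei (9 of 11 lower, median -0.45, adjusted p = 9.01e-15, and adjusted p = 0.646 with an estimated correlation). Of its members 5 passed adjusted over the list alone, Sgk1, Fkbp5 (-2.00 ± 0.40), Zbtb16, Pdk4 (-1.35 ± 0.30) and Tsc22d3, and Sgk1 alone over all genes. Cholesterol synthesis genes fell as a list (20 of 22 lower, median -0.33, adjusted p = 7.04e-05, and adjusted p = 0.646 with an estimated correlation), with 0 members adjusted over the list alone and Fdft1 at -0.48 ± 0.19, Msmo1 at -0.48 ± 0.19 and Sqle at -0.49 ± 0.25. That call ended without mTBI 1 (adjusted p = 0.0738). Sodium and potassium channels rose as a list (21 of 27 higher, median 0.17, adjusted p = 0.043, and adjusted p = 0.646 with an estimated correlation), with Kcnab1 passing adjusted over the list alone and Scn8a at 0.62 ± 0.23, Kcnip1 at 0.90 ± 0.48 and Kcna2 at 0.40 ± 0.22. That call ended with the replicate block (adjusted p = 0.116), with doublets kept (0.0534) and without sham 2 (0.257), and turned without mTBI 2 (0.85).

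The GABA list (20 measured, adjusted p = 0.658) and the burst-firing list (12 measured, adjusted p = 0.604) did not pass in oligodendrocyte-like nuclei, each with 0 genes adjusted over the list alone. Among the 4 smallest p-values of each were those of Gabra2 (0.83 ± 0.46) and Gad2 (0.27 ± 0.26), and of Ryr3 (-1.13 ± 0.38), Hcn2 (0.30 ± 0.15) and Ryr2 (0.59 ± 0.47).

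In oligodendrocyte precursor-like nuclei, 4 genes passed. Zbtb16, a zinc finger gene induced by glucocorticoids, fell by 3.35 ± 0.52 on the log2 scale (n = 2 libraries per group, adjusted p = 5.7e-07), from 146 and 173 CPM in sham to 0 and 19.0 in mTBI, or from 30 and 46 UMIs to 0 and 6. Gpr17, a receptor gene of committed precursors, rose 2.81-fold (1.49 ± 0.29, adjusted p = 0.00078), from 58.5 and 162 CPM to 163 and 393. mt-Co3 and mt-Co1 fell by 1.46 ± 0.31 (adjusted p = 0.00329) and 1.42 ± 0.29 (adjusted p = 0.0013). Zbtb16 (ENSMUSG00000066687) lies on the minus strand of chromosome 9 from 48654297 to 48836222. Mink1 was next (1.54 ± 0.39, adjusted p = 0.0725). Gpr17 overlaps another gene on the opposite strand and is uncertain for that reason. mTBI 1 held 15 of these nuclei.

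Of 5319 genes 225 had an unadjusted p under 0.05 in precursor-like nuclei, and 0 passed under DESeq2 (18). Zbtb16 passed in 10 of 11 other settings (adjusted p from 5.70e-07 to 0.771). Gpr17 did not pass with the replicate block (adjusted p = 0.0735), with doublets kept (0.151), without sham 1 (0.998, at a log2 of 0.94) or without mTBI 2 (0.889, at 0.46), mt-Co3 not with the block (0.0735), with doublets kept (0.112), without sham 1 (0.998), sham 2 (0.0612) or mTBI 2 (0.784), and mt-Co1 not without sham 1 (0.998), sham 2 (0.0502) or mTBI 2 (0.549). The block called 2 genes, and 1, 2, 7 and 5 passed without sham 1, sham 2, mTBI 1 and mTBI 2.

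The glucocorticoid response list fell in precursor-like nuclei too (4 of 6 lower, median -0.49, adjusted p = 0.0148, and adjusted p = 0.810 with an estimated correlation), with Zbtb16 alone passing, both over all genes and adjusted over the list alone, and Fkbp5 at -1.0 ± 0.64, Klf9 at -0.69 ± 0.47 and Nr3c1 at 0.33 ± 0.29. The call ended without mTBI 1 (adjusted p = 0.111). Whether the change of these genes differed between precursor-like and oligodendrocyte-like nuclei was not tested. The complement list (7 measured, adjusted p = 0.852, median 0.14, mean -0.06, test upward), the GABA list (13 measured, adjusted p = 0.329) and the burst-firing list (11 measured, adjusted p = 0.665) did not pass, each with 0 genes adjusted over the list alone. Their smallest p-values were those of Cd46 (-0.91 ± 0.52), Csmd2 (0.21 ± 0.19), Susd4 (-0.36 ± 0.34) and Csmd3 (0.14 ± 0.14), of Gabrb1 (-0.49 ± 0.25), Gad1 (0.69 ± 0.36), Gabra2 (1.04 ± 0.58) and Slc12a2 (0.63 ± 0.39), and of Kcnn2 (-0.56 ± 0.31), Kcnma1 (-0.28 ± 0.20), Kcnt2 (0.42 ± 0.33) and Ryr2 (0.36 ± 0.36).

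**Figure D3:**
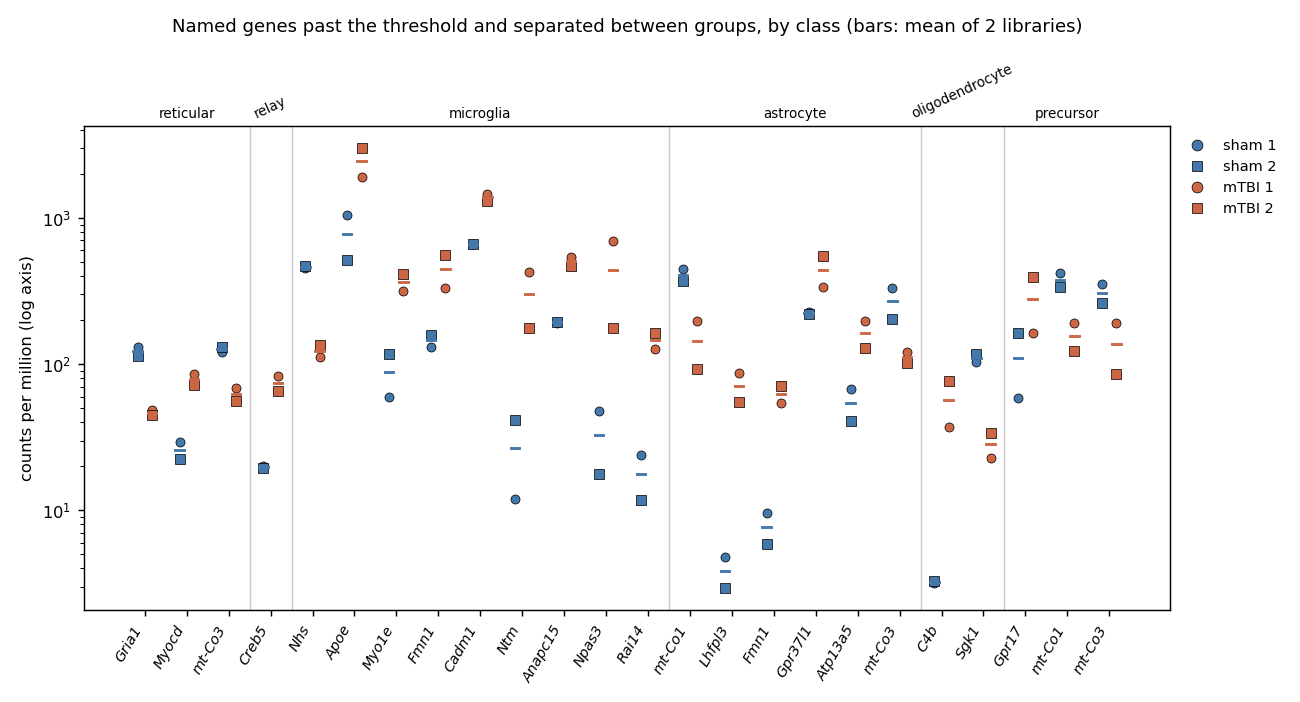
CPM on a log axis of the named genes past the threshold with both mTBI libraries on one side of both sham libraries, by class, with bars for the mean of 2 libraries, a circle for replicate 1 and a square for replicate 2. Genes with a library at 0 (Bcas1os2, Wdr17, Trpm3 and Zbtb16) are left out because of the log axis, and C4b in oligodendrocyte-like nuclei stands at 3.20 and 3.29 CPM in sham and 37.2 and 76.1 in mTBI.

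Mitochondrially encoded transcripts fell as a list in each of the 6 classes tested and in all nuclei summed. The median log2 change was -0.95 in reticular-like neurons (11 of 11 lower, adjusted p = 1.49e-18), -0.93 in relay-like neurons (12 of 12, 5.53e-23), -1.03 in microglia-like nuclei (7 of 7, 8.50e-07), -1.0 in astrocyte-like nuclei (8 of 8, 2.39e-13), -0.98 in oligodendrocyte-like nuclei (12 of 13, 4.08e-17), -1.41 in precursor-like nuclei (8 of 8, 8.81e-13) and -0.85 in all nuclei (13 of 13, 2.94e-24). The adjusted p lay between 0.490 and 0.934 with an estimated correlation. Adjusted over the list alone 8, 9, 5, 4, 10, 6 and 10 members passed in that order, against 1, 0, 0, 2, 0, 2 and 0 over all genes. Among the 4 members with the smallest p in each class, values not yet given ranged from -0.85 ± 0.25 for mt-Nd4 in oligodendrocyte-like nuclei to -1.76 ± 0.34 for mt-Nd5 in relay-like neurons. With the replicate block further members passed over all genes, mt-Co2 (adjusted p = 0.00407), mt-Co1 (0.00418) and mt-Atp6 (0.0179) in reticular-like neurons, mt-Co2 (5.25e-08), mt-Co3 (1.90e-09), mt-Nd2 (0.0011) and mt-Nd5 (0.00311) in relay-like neurons, and mt-Co3 (0.00314) and mt-Co1 (0.01) in microglia-like nuclei. Median mitochondrial shares per barcode were 0.0832% and 0.0652% in sham and 0.0536% and 0.0248% in mTBI, and these transcripts are made in mitochondria, outside the nucleus. In microglia-like nuclei the call ended without mTBI 2 (adjusted p = 0.0851).

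Nuclear-encoded oxidative phosphorylation genes were lower as a list in 3 classes and in all nuclei, with small median changes. They stood at a median of -0.21 in microglia-like nuclei (29 of 39 lower, adjusted p = 0.00874, and adjusted p = 0.763 with an estimated correlation), -0.12 in astrocyte-like nuclei (41 of 70, 0.0428 and 0.825), -0.16 in oligodendrocyte-like nuclei (58 of 76, 6.91e-08 and 0.737) and -0.13 in all nuclei (57 of 76, 2.07e-05 and 0.915). Ribosomal protein genes were lower in astrocyte-like nuclei (44 of 69, median -0.14, adjusted p = 0.00152, and adjusted p = 0.825 with an estimated correlation), oligodendrocyte-like nuclei (44 of 75, -0.04, 0.000493 and 0.796), precursor-like nuclei (37 of 55, -0.23, 0.00355 and 0.863) and all nuclei (55 of 75, -0.08, 0.000373 and 0.915). Adjusted over the list alone 0 members of either list passed in any of these. Examples were Uqcrb (-0.89 ± 0.49) in microglia-like nuclei, Cycs (-1.53 ± 0.65) and Rps12 (-0.94 ± 0.44) in astrocyte-like nuclei, Cox6a1 (-0.61 ± 0.29) and Rps29 (-0.42 ± 0.22) in oligodendrocyte-like nuclei and Rps21 (-1.30 ± 0.50) in precursor-like nuclei.

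These 2 lists depended on mTBI 1. Without it the oxidative phosphorylation list turned in microglia-like nuclei (adjusted p = 0.555), oligodendrocyte-like nuclei (0.000449) and all nuclei (0.000149), the ribosomal list turned in oligodendrocyte-like nuclei (5.52e-12) and all nuclei (0.000726), and neither passed in astrocyte-like nuclei (0.995 each) nor the ribosomal list in precursor-like nuclei (0.999). Without sham 1 the adjusted p was 0.0514 for oxidative phosphorylation in microglia-like nuclei and 0.582 for ribosomal genes in precursor-like nuclei. With doublets kept the oxidative phosphorylation list did not pass in microglia-like nuclei (0.278), astrocyte-like nuclei (0.161) or all nuclei (0.0783), nor the ribosomal list in all nuclei (0.804).

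In all nuclei summed, 0 of 18776 genes passed with edgeR, where 573 had an unadjusted p under 0.05, and DESeq2 called 6. The smallest p-values were those of Myocd (1.30 ± 0.15, adjusted p = 0.623), C4b (2.38 ± 0.29, 0.623), Cntnap5b (-0.92 ± 0.12, 0.692), Zbtb16 (-1.06 ± 0.15, 0.718) and the pro-apoptotic gene Hrk (2.26 ± 0.34, 1.00). Without mTBI 1 the count was 364, without mTBI 2 28, without sham 1 1 and without sham 2 0 (244 at an unadjusted p under 0.05). As lists, complement genes (20 of 25 higher, median 0.25, adjusted p = 3.03e-06), disease-associated microglia genes (19 of 23, 0.45, 1.96e-09), disease-associated oligodendrocyte genes (8 of 12, 0.20, 4.76e-05) and axon injury genes (13 of 15, 0.11, 0.000446) rose and glucocorticoid response genes fell (9 of 12 lower, -0.20, 0.000373). The adjusted p was 0.467 for these lists with an estimated correlation, and 0.915 for the axon injury list. Adjusted over the list alone C4b passed in the complement list, C4b and Cd63 (0.64 ± 0.18) in the disease-associated oligodendrocyte list, Atf3 (2.13 ± 0.42) in the axon injury list, Zbtb16 in the glucocorticoid list and 0 genes in the disease-associated microglia list. Without mTBI 2 the disease-associated microglia list had an adjusted p of 0.257 and the axon injury list turned (0.0617).

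**Figure D4:**
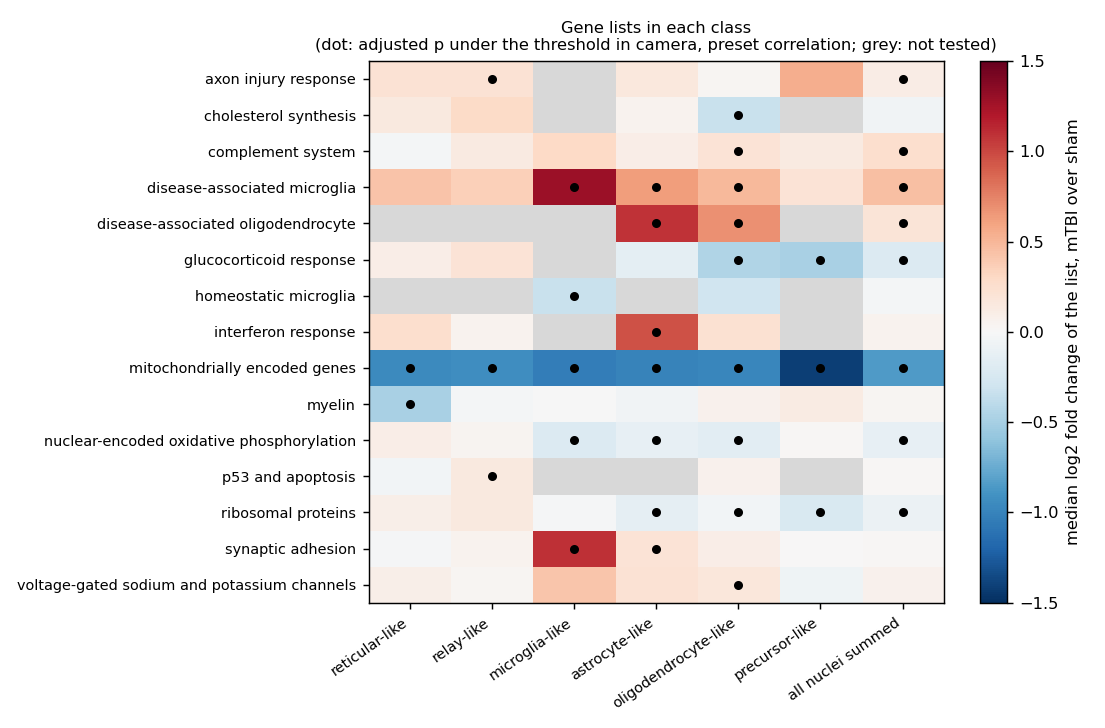
Median log2 fold change, mTBI over sham, of the 15 gene lists that passed in at least 1 class, as a colour scale, with a dot where the list passed at the preset correlation and grey where it was not tested. The mitochondrially encoded list is negative in each column, from -0.85 to -1.41.

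13 of the 28 tested lists passed in no class. Their smallest adjusted p over classes was 0.0971 for the perineuronal net, 0.176 for immediate early genes, 0.219 for synaptic vesicle release, 0.316 for burst-firing channels, 0.329 for the GABA list, 0.454 for heat shock and unfolded protein genes, 0.559 for the circadian clock, 0.620 for A2 and 0.697 for A1 astrocyte genes, and 0.499 each for antigen presentation, glutamate receptors, pan-reactive astrocyte and vascular genes. Single members of these lists passed adjusted over the list alone in several classes, among them, in relay-like neurons, 5 that rose and 2 that fell of 14 measured immediate early genes, and Per2 and Cry1 of the circadian list, which fell. 15 lists passed in at least 1 class. With doublets kept 5 of the 13 passed in a class, at a smallest adjusted p of 1.56e-08 for antigen presentation, 0.00492 each for glutamate receptors and burst-firing channels, 0.0205 for synaptic vesicle release and 0.0488 for pan-reactive astrocyte genes. Antigen presentation, glutamate receptors and burst-firing channels passed there in microglia-like nuclei. In that setting the class took in clusters of 104 and 85 nuclei with median UMIs of 14121 and 4423, against 1618 in its cluster of 421.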

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

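The tests in this part were planned before the data were examined, except the naming of clusters from summed CPM alone, which was chosen after the result was seen. The response to injury differed between reticular-like and relay-like neurons for 16 genes, tested as the interaction of class and treatment within libraries. On the log2 scale, reticular-like minus relay-like, the differences with the smallest p-values were -1.76 for Creb5, -1.69 for Gria1, -1.51 for Pdzrn4, -4.41 for Ecel1 and -1.21 for Luzp2. Creb5 passed in relay-like and Gria1 in reticular-like neurons when each class was tested alone, and Pdzrn4, Ecel1 and Luzp2 passed in neither. 0 genes passed without mTBI 2, the larger of the injured libraries, and 36, 71 and 69 passed without sham 1, sham 2 and mTBI 1. With doublets kept 0 passed. Ecel1, a reticular marker, differed by -1.89 with an adjusted p of 0.851 under the naming from summed CPM alone, which leaves cluster 14 out of the relay-like class. No explanation of these differences was tested.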

How the results depend on the processing

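The naming versions, the removal of clusters mostly from 1 library and the list tests without each library, with doublets kept and under the naming from summed CPM alone were chosen after the data were seen. The cause was not tested for any change given here, except that thinning lowers the number of UMIs alone. Across the alternatives for single genes, classes and lists, apart from C1q in microglia-like nuclei, the counts of genes and lists, and the other results that answer a comparison, 2551 values kept their direction and their side of the threshold, 212 passed where they had not, 234 no longer passed and 58 turned. The 2551 include genes and lists that did not pass in the main fit and stayed so, while only results that had passed could be among the 234. These totals therefore do not give the share of calls that held. A further 3 turned, those of C1qa, C1qb and C1qc in microglia-like nuclei without mTBI 2. C4b in oligodendrocyte-like nuclei passed in 12 of 12 settings and Creb5 in relay-like neurons in 11 of 13. By contrast, Rai14 in microglia-like nuclei passed in 5 of 10 and mt-Co3 in reticular-like neurons in 4 of 12. In mTBI 1 precursor-like, astrocyte-like and microglia-like nuclei numbered 15, 20 and 26.

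With the replicate block, which pairs libraries by Chromium run, 22 genes passed in reticular-like neurons, 290 in relay-like neurons, 60 in microglia-like, 6 in astrocyte-like and 2 in precursor-like nuclei. Of the calls of genes named by the rule and of lists, counted per class, 29 gene calls passed in the paired fit that had not. A further 6 calls of genes and lists no longer did. Each is given with its result. Of the 10 genes that passed in astrocyte-like nuclei 5 were kept. The sodium and potassium channel list was gained in microglia-like nuclei, 36 list calls passed instead of 37, and the block changed no other call among these. RLE size factors gave 3 genes in reticular-like neurons, 5 in astrocyte-like and 1 in oligodendrocyte-like nuclei. DESeq2 gave 1 in reticular-like and 25 in relay-like neurons, 0 in microglia-like nuclei (74 at an unadjusted p under 0.05), 0 in astrocyte-like (33), 5 in oligodendrocyte-like, 0 in precursor-like (18) and 6 in all nuclei, and turned Gphn in microglia-like nuclei (-0.0313). Without a filter on low counts 51 genes passed in reticular-like and 302 in relay-like neurons, 49 in microglia-like, 17 in astrocyte-like and 65 in oligodendrocyte-like nuclei, 102 in all nuclei and 87 in the test of reticular-like against relay-like neurons. With UMIs thinned to the shallowest library edgeR gave 0 genes in reticular-like neurons (317 at an unadjusted p under 0.05), relay-like neurons (745) and microglia-like nuclei (144), so depth limits these counts. A minimum of 1000 UMIs gave 3 in reticular-like neurons and 0 in microglia-like nuclei (290). The lower clustering resolution gave 7 in precursor-like nuclei, and leaving out the cluster mostly from mTBI 2 gave 1 in oligodendrocyte-like nuclei. Of the 37 list calls, 0 passed with an estimated correlation and 0 with fry.

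With doublets kept edgeR gave 0 genes in reticular-like neurons (414 at an unadjusted p under 0.05), relay-like neurons (910), microglia-like (370) and astrocyte-like nuclei (285) and 0 in the test between the neuron classes. These log2 values then turned: in relay-like neurons Csmd2 to -0.11, Cd59a to -0.0442, Gabra2 to -0.0936, Kcnk2 to -0.38 and Phlda3 to -0.0798, in microglia-like nuclei Ntm to -0.10, Ndufa10 to -0.0873, Gabrb1 to -0.59, Gphn to -0.11, Slc12a2 to -0.30, Pex5l to 0.0393, Atp2a2 to -0.18, Kcnma1 to -0.0477, Nlgn1 to -0.17, Lrrc4c to -0.16 and Cadm2 to -0.30, in astrocyte-like nuclei Pex5l to -0.49, and the numbers of oligodendrocyte-like nuclei to 0.0224 and of relay-like neurons to -0.11. With doublets kept microglia-like nuclei took in clusters of 104 and 85 nuclei with higher doublet scores. In that setting 46 list calls passed and the synaptic adhesion list turned in microglia-like nuclei (adjusted p = 0.000635). Under naming from summed CPM alone 35 passed, without the axon injury (0.338) and p53 and apoptosis (0.296) lists in relay-like neurons. Under naming from mean CPM alone the number of reticular-like neurons turned to -0.58.

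Leaving out 1 library in turn assumes that the lone library of a group varies like the other group. The number of genes then lay between 4 and 196 in reticular-like neurons, 2 and 837 in relay-like neurons, 0 (without mTBI 1, 357 at an unadjusted p under 0.05) and 65 in microglia-like nuclei, 3 and 68 in astrocyte-like, 8 and 448 in oligodendrocyte-like, 1 and 7 in precursor-like and 0 (without sham 2, 244) and 364 in all nuclei, and between 0 and 71 in the test of reticular-like against relay-like neurons. Most of the highest counts came without mTBI 1. Between 39 and 64 lists passed.

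Log2 values that turned had these ranges. In reticular-like neurons Csmd3 ran from -0.53 to 0.0178 and Slc32a1 from -0.0904 to 0.82. In relay-like neurons Cd59a ran from -1.10 to 0.83. In microglia-like nuclei the ranges were -0.91 to 1.02 for C1qa, -0.32 to 0.62 for C1qb, -1.19 to 0.89 for C1qc, -0.067 to 0.47 for Gabbr1, -1.08 to 0.45 for Gphn, -0.12 to 0.58 for Atp2a2 and -0.14 to 0.40 for Kcnma1. In astrocyte-like nuclei they were -0.18 to 1.02 for Clu, -1.43 to 1.19 for Csmd1, -0.0587 to 1.05 for Apoe, -0.10 to 0.88 for Ctsl, -0.0447 to 1.33 for Eif2ak2, -2.36 to 1.56 for Cntnap2 and -0.63 to 1.39 for Ntng1. In oligodendrocyte-like nuclei Rpl30 ran from -0.0082 to 0.75, in precursor-like nuclei Ryr2 from -0.0069 to 0.95, and in all nuclei C1qa from -0.14 to 0.78 and Gabra3 from -0.10 to 0.61. The log2 number of nuclei ran from -0.77 to 0.10 for astrocyte-like, -0.28 to 0.15 for oligodendrocyte-like, -0.24 to 0.40 for relay-like and -0.27 to 1.07 for reticular-like nuclei.

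Lists whose direction turned had these adjusted p ranges, which pool fits of both directions. A small value there need not be in the direction of the main fit. The axon injury list ran from 1.77e-12 to 0.0307 in relay-like neurons and 2.27e-11 to 0.0617 in all nuclei, and turned without mTBI 2. The disease-associated microglia list ran from 2.41e-08 to 0.339 in astrocyte-like and 1.44e-19 to 0.85 in oligodendrocyte-like nuclei, and the sodium and potassium channel list from 3.02e-05 to 0.85 in the latter, all turning without mTBI 2. The oxidative phosphorylation list ran from 2.59e-05 to 0.555 in microglia-like nuclei, 5.53e-49 to 0.000449 in oligodendrocyte-like nuclei and 2.40e-48 to 0.000173 in all nuclei. The ribosomal list ran from 4.39e-44 to 0.0399 in oligodendrocyte-like nuclei and 3.14e-31 to 0.0261 in all nuclei. Both turned without mTBI 1.

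Endothelial-like nuclei were not tested, because mTBI 1 held 7 of them. At the lower clustering resolution the endothelial-like cluster held 154 nuclei, against 120 in the main clustering, and no mural-like cluster stood apart. The mural markers Rgs5 and Vtn were among its leading genes. That class, which may thus hold the mural-like nuclei too, reached the minimum, and edgeR gave 0 genes (58 at an unadjusted p under 0.05). Reticular-like neurons were not testable under the naming from mean CPM alone.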

Other observations

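The test of mixed nuclei was added after the marker test had been read and before its own value was known, the 4 C4b tests were chosen after the result was seen, and the remaining tests were set beforehand. Beyond the genes already named, further genes whose injury response differed between reticular-like and relay-like neurons were chosen after their values were seen. On the log2 scale the synaptic vesicle protein gene Sv2c stood at -0.22 in reticular-like and 1.48 in relay-like neurons (difference -1.68 ± 0.26, adjusted p = 0.00683 by edgeR), the secreted factor gene Tafa1 at -2.41 and 0.27 (-2.71 ± 0.41, 0.0065), the engulfment adapter gene Gulp1 at -1.18 and 0.44 (-1.60 ± 0.26, 0.0128), Car10 at -1.58 and -0.16 (-1.45 ± 0.25, 0.0228), the glutamate transporter gene Slc1a2 at -0.28 and 0.74 (-1.12 ± 0.21, 0.0392) and Kcnip4 at -0.89 and 0.10 (-0.93 ± 0.18, 0.0475). Ptchd4 went the other way, at 0.21 and -0.76 (1.00 ± 0.15, 0.00683), and Ust stood at -0.70 and 0.61 (-1.35 ± 0.26, 0.0475). Under the naming from summed CPM alone, added after the data were seen, which leaves cluster 14 out of the relay-like class, Sv2c (-1.35, adjusted p = 0.0690) and Ust (-1.32, 0.0619) did not pass, and cluster 14 held 3 of 42 and 88 of 329 relay-like Sv2c UMIs of mTBI 1 and mTBI 2.

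In endothelial-like nuclei, C1q made up 21 and 23 UMIs in sham and 1 and 2 in mTBI, or 156 and 83.3 CPM against 24.8 and 7.05, the highest level of any class after microglia-like nuclei in the sham libraries. These nuclei numbered 26, 52, 7 and 35 and the difference was not tested. In astrocyte-like nuclei C4b stood at 31.1 and 32.2 CPM in sham and 0 and 91.6 in mTBI, with 7, 24, 0 and 61 UMIs.

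C4b rose in oligodendrocyte-like nuclei from 0.00770 and 0.00657 UMIs per nucleus to 0.128 and 0.167. RNA from other cells, carried into every droplet alike, would have given relay-like nuclei at least 0.5 times as many, and the higher ratio of the mTBI libraries was 0.0644, which argues against that source. Without cluster 7, which came mostly from mTBI 2, the change was 3.56 (adjusted p = 0.016), so that cluster was not the whole cause, under a bound reworded after the value was seen because the first, a shift within 1 standard error, decided neither way. A difference between Chromium runs, each of which by the replicate numbers holds a library of each group, would shift both alike. C4b was 11.4 and 24.4 times as high in mTBI as in sham within the runs, in unscaled CPM. As C4b was picked for standing higher in both mTBI than in both sham libraries, such ratios were given beforehand, and the run test cannot decide. Reads exchanged with the near-identical copy C4a, at 0 to 2 UMIs per library in these nuclei, would leave the sum of the copies alike. That sum was 11.4 and 20.4 times as high, which argues against such an exchange as the source of the rise. Which copy the reads come from is not known. A response of oligodendrocytes to injury is a hypothesis, found and tested on the same data.

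Mitochondrially encoded transcripts were lower after mTBI in each class tested, with medians from -0.93 to -1.41. Cytoplasmic RNA carried into every droplet would give deep and shallow nuclei like numbers, and a relay-like to microglia-like ratio under 2 was set for that source and above 0.5 times the depth ratio against it. The lowest ratio was 2.22, against depth ratios of 6.56 to 7.78, so it met neither bound and these sources cannot be told apart. Per relay-like nucleus there were 6.83 and 5.62 mitochondrial UMIs in sham and 7.25 and 2.51 in mTBI, so mTBI 1 was not below sham on that scale. Nuclei purity per library and a change in the cells both stay open, the latter untested.

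In microglia-like nuclei after mTBI, Wdr17, Ntm, Npas3 and Trpm3 rose, and astrocyte and precursor markers were higher. The astrocyte markers stood at 2.69 and 1.48 times the sham mean in mTBI 1 and mTBI 2, and as a bound of 2 had been set for both, that test left the source open. The 1 in 10 nuclei with most UMIs of these 4 genes held 98.7% of them in mTBI 1 (3 of 26 nuclei) and 94.0% in mTBI 2 (20 of 196), against 95% ranges of 23.3% to 35.2% and 29.3% to 38.3% in 1000 draws that spread the UMIs by depth. This is consistent with a few mixed nuclei, such as microglia with astrocyte RNA, as the source of these 4 genes. It does not bear on the other 7 genes that passed, and microglia that express these genes or take up astrocyte material were not tested.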
